A study of Homo sapiens with 32 samples.

How the data were processed

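Total RNA from 32 established human acute myeloid leukaemia (AML) cell lines was measured on Affymetrix expression arrays with 54675 probe sets, 1 array per line. The deposited values are probe set intensity on a linear scale, made by the authors with Affymetrix Expression Console, which the submitters' processing notes name; the version and the summarization method are not stated in the sources used here. The authors' values were checked for scaling: the mean after trimming 2% of probe sets at each end lay between 500 and 500.1 on every array. Response to PIM inhibitors, which the design text names, was not used here.

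Intensities were transformed as log2(signal + 16) with no further scaling. Of the probe sets, 41091 had 1 gene symbol in the platform's name table, 1801 had several, 11721 were not listed and 62 were controls. Of those with 1 symbol, 54 had no match in the RefSeq gene table. Probe sets with 1 symbol stood for 19775 genes, and where a gene had several (10523 genes) the one with the highest mean over the 32 arrays was used. A gene was tested if it lay above the median of all probe sets and arrays, a log2 level of 6.73, in at least 3 units, which left 15455 genes. Only 3 of 13 members of the HOXA list, which also holds cofactor genes, were tested under these rules. The cofactor genes MEIS1 and PBX3 were among the 3, so results for this list say little on the HOXA genes themselves.

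Lines were the units of testing. KG-1 with KG-1A, and HL-60 with PLB-985, are sublines of 1 donor each, so each pair was averaged, which gave 30 units. The entry written KG1 with a question mark in the growth protocol was read as KG-1A. With 1 array per line, p-values measure spread between these lines, and the number of arrays limits the precision. R 4.3.3 and limma 3.58.1 were used for the models, and matplotlib 3.10.9 with pandas 2.3.3 for the plots.

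The 4 model comparisons were fixed before the data were examined, as were the choices, gene lists and alternatives named here unless stated otherwise. For PIM1, PIM2 and PIM3, the 3 kinases that PIM inhibitors act on, limma (lmFit, then eBayes with a mean-variance trend) gave each gene's slope on the log2 level of that PIM gene over the 30 units, leaving out the PIM gene itself. The last comparison set 4 lines grown with an added cytokine against 23 units whose stated medium names none, leaving out 3 lines with no stated medium. All tests were two-sided, and p-values were adjusted by Benjamini and Hochberg's method, with 0.05 as the threshold. Each error after a ± sign is a standard error.

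In all, 23 gene lists were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. The lists were erythroid, megakaryocyte and platelet, monocyte and macrophage, neutrophil and eosinophil granule, stem and progenitor, HOXA, HOXB, STAT5-regulated, JAK-STAT component, cytokine receptor, MAPK feedback, MYC target, mTOR and translation control, PIM substrate, BCL2 family, interferon-induced, MHC class II, cell cycle, stress and hypoxia, B cell, T and NK cell, stromal and epithelial, and AML fusion partner and overexpressed genes. Some genes stand in more than 1 list. A list's score in a unit is the mean over its tested genes of the log2 level minus the gene's mean over units. In the 20 list tests that passed camera, the median, the mean and the test had the same sign; in 10 of the 72 that did not, they differed.

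Correlations across units formed a family of 37 relations, each with Pearson's r and Spearman's rho. Their p-values came from permutation tests with 100000 resamples, for which 1e-05 is the smallest value possible, or from exact permutation tests for the 8 arrays of high GAPDH ratio. Each r was computed again without the 2 units farthest from the median of the first measure, and within the arrays of low and of high GAPDH 3'/5' ratio. The permutation p-values given for these repeats are not adjusted.

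Genes named in the text were chosen by rule, those ranked by spread or by gap between units from the tested genes alone. They are the 3 PIM genes; the 15 genes of largest standard deviation (SD), of which 3 found only on 1 sex chromosome are not reported; and the 15 with the largest gap between the highest and the second highest unit. To these come up to 10 genes each way with the largest slope among those passing, up to 4 members of each list that passed or held a passing gene, and the 2 most variable members of each list. Other genes named were chosen after their values were seen, and the text says so.

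RNA quality was read from the control probe sets for GAPDH. A ratio of the 3' to the 5' probe set above 2 was taken as high, a limit chosen after seeing the data. The same ratio for ACTB did not order all arrays alike. It was 3.21 for SHI-1 and 2.6 for OCI-AML3, both low by GAPDH, and 2 for THP-1, high by GAPDH. Arrays of low GAPDH ratio are thus not all shown to be intact. The models were tested on simulated data with 15455 genes and 100 changed genes per size. A change of 1 log2 unit per SD of the PIM gene was recovered for 85% of genes for PIM1, 84% for PIM2 and 84% for PIM3. For the cytokine comparison, a difference of 1 log2 unit was recovered for 21% and of 2 for 66%. False calls made up 5.13%, 4.66%, 8.04% and 7.45% of calls in the PIM1, PIM2, PIM3 and cytokine simulations. The simulated noise was drawn independently for each gene, so these shares do not show the rate of false calls among genes that vary together. On the real values, random orders gave up to 3867 calls for PIM2 and up to 1998 for cytokine.

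The alternatives were quantile normalization, centring each array on its median, other choices of probe set, filter and pseudocount, all 32 lines as samples, eBayes without a trend or with a robust trend, and the first principal component as a covariate. Others left out the 2 farthest units, replaced the PIM level by normal scores of its ranks, or kept only lines in RPMI 1640 without cytokine. Settings without NOMO-1 and GF-D8, without the 8 arrays of high GAPDH ratio, with the log2 GAPDH ratio as a covariate, without each unit in turn, list tests with median centring, and correlations in the 24 units below the largest gap in erythroid scores were added after seeing the data.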

Results

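The arrays covered 32 AML cell lines, 1 array each, with no treatment. In the growth conditions given, 21 lines grew in RPMI 1640 and 4 in IMDM with no cytokine named. OCI-AML2, OCI-AML3 and OCI-AML5 grew in alpha-MEM with GM-CSF or SCF, F-36P grew in RPMI 1640 with IL-3 at 5 ng/ml, and no medium was given for MOLM-13, MOLM-16 and MV4-11. The stated purpose of the series was to relate expression to the response to PIM inhibitors. Response was not used here, so the comparisons ask which genes vary with the level of each drug target, PIM1, PIM2 and PIM3.

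Signal differed between arrays in ways that no label gives. On 30 arrays the median signal was 68.2 to 115.4, while it was 198.4 for NOMO-1 and 243.3 for GF-D8. The trimmed mean was the same on every array, so the higher medians go with fewer low signals. Only 5.99% of probe sets on NOMO-1 and 3.54% on GF-D8 lay below 16, against 16.1% to 24.7% on the 30. Genes of low level thus read higher on these 2 arrays. NOMO-1 and GF-D8 had mean correlations with the other arrays of 0.731 and 0.652, against 0.846 to 0.883 for the other 30. The ratio of the 3' to the 5' GAPDH probe set, which rises as RNA is degraded, was 0.871 to 1.24 on 24 arrays. It was above 2 on 8 arrays, namely GDM-1, HL-60, ML-2, NB-4, MOLM-13, THP-1, NOMO-1 and GF-D8, with values from 2.42 to 7.08.

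PIM1, a kinase gene induced by STAT5, spanned the widest range of the 3 PIM genes. Its log2 level (probe set 209193_at) was 10.63 on average (SD 2.14, n = 30 units), from 7.16 in KMOE-2 to 13.94 in MOLM-16, a 109.6-fold range. PIM2 (204269_at) averaged 9.36 (SD 0.865), from 8.17 in GF-D8 to 12.06 in OCI-M1, a 14.9-fold range in which HEL was next highest at 11.09. PIM3 (224739_at) averaged 11.19 (SD 0.577), from 9.85 in KG-1/KG-1A to 12.47 in NB-4, a 6.14-fold range. Lines rich in PIM1 included OCI-M1 at 13.64, FKH-1 at 13.23 and EOL-1 at 13.15.

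**Figure D1:**
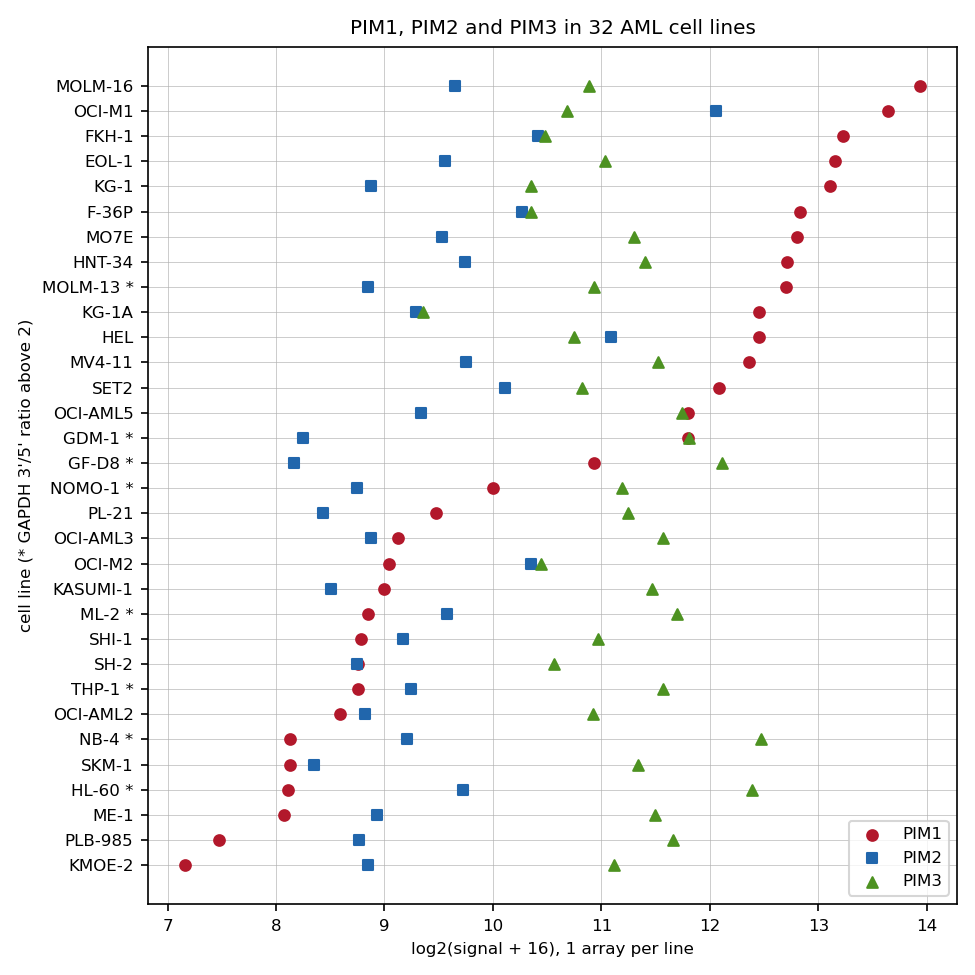
Level of PIM1, PIM2 and PIM3 as log2(signal + 16) on the x axis for each of the 32 cell lines on the y axis, ordered by PIM1, 1 point per array; asterisks mark the 8 lines with a GAPDH 3'/5' ratio above 2. PIM1 runs from 7.16 in KMOE-2 to 13.94 in MOLM-16.

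PIM3 level moved with the GAPDH ratio. Over 30 units, r of PIM3 with the log2 ratio was 0.604 (permutation p = 0.00033), while rho was 0.308 (p = 0.0976); without NB-4 and GDM-1, r was 0.469 (p = 0.0118). For PIM1 the r was -0.186 (p = 0.326, rho = 0.0242, p = 0.901) and for PIM2 it was -0.291 (p = 0.115, rho = -0.0131, p = 0.946).

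**Figure D2:**
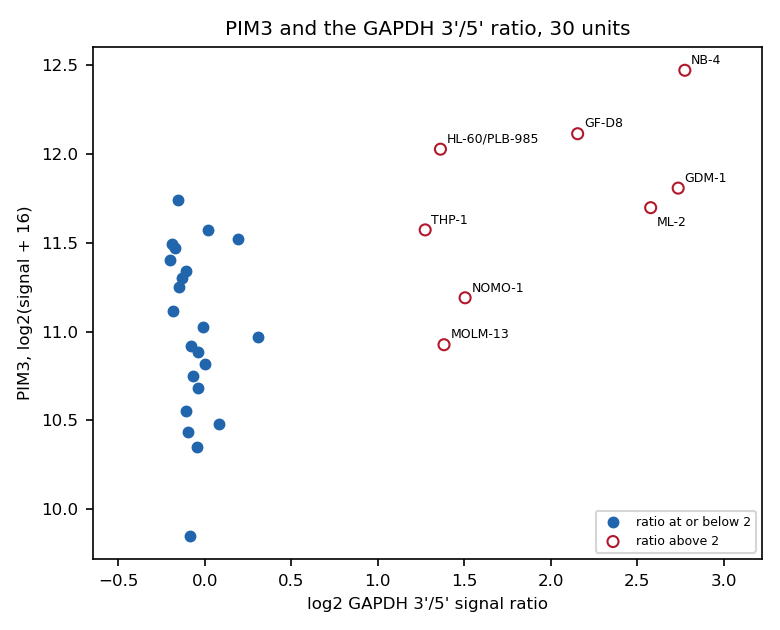
PIM3 level as log2(signal + 16) on the y axis against the log2 ratio of the 3' to the 5' GAPDH probe set on the x axis, 1 point per unit (30 units); open circles are units with a ratio above 2. NB-4 has the highest PIM3 level, 12.47, and r is 0.604.

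The most similar lines were MOLM-13 and MV4-11, both known to carry a KMT2A fusion. Their r across 15530 genes was 0.937, the highest of 496 pairs, followed by EOL-1 with MV4-11 at 0.928. The sublines HL-60 and PLB-985 ranked 3 with r = 0.92, and KG-1 and KG-1A ranked 8 with r = 0.907. Genes are not independent replicates, so these values carry no test. The median absolute log2 difference over genes was 0.579 between HL-60 and PLB-985, 0.471 between KG-1 and KG-1A, and 0.645 over all pairs. The 61 pairs with NOMO-1 or GF-D8 had a median r of 0.623 and the other 435 pairs one of 0.827.

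The genes that varied most between lines included several of granule proteins. ELANE (neutrophil elastase) had the largest SD, 4.29 on the log2 scale, followed by BEX3 with 4.16, MPO (myeloperoxidase) with 3.96 and PRTN3 (proteinase 3) with 3.91. LAMP5, S100A8, AZU1, CHI3L1, CYTL1, CALHM6, CES1 and RNASE2 had SDs from 3.39 to 3.76. ELANE was highest in ML-2 at 15.43 and lowest in MOLM-16 at 4.39. S100A8, a calcium-binding protein gene of monocytes and neutrophils, was highest in NOMO-1 at 16.09.

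Several genes were high in a single line. MAGEA4, a cancer-testis antigen gene, was at least 42.7-fold higher in KMOE-2 than in the next unit, GF-D8, where its log2 level of 8.06 was near the array median of 8.018. MX1 (interferon-induced) was 18.5-fold higher in KMOE-2 than in NOMO-1, an array of high median signal. There its log2 level of 8.939 lay 1.2 above the array median. MAGEA6 was 11.6-fold higher in KMOE-2 than in the next unit. The serotonin receptor gene HTR2B was 31.7-fold higher in SH-2, the defensin gene DEFA4 27.2-fold in ML-2, and C1QTNF4 22.1-fold in KASUMI-1. HEY1 (19.1-fold) and MCAM (11.6-fold) stood out in OCI-M2, the homeobox gene MNX1 (19-fold) in GDM-1, and ORM1 (17.1-fold) in OCI-AML2. SERPINB3 in FKH-1 was at least 13.7-fold above GF-D8, where its log2 level of 8.522 lay 0.504 above the array median of 8.018. MAGEA1 in HEL was 12.8-fold above the next unit. SYBU in OCI-M1 was at least 13.9-fold and ESX1 in SKM-1 at least 12.4-fold above NOMO-1 and GF-D8 in turn, where these genes lay below the array median. TMEFF2 was 12.2-fold higher in GF-D8 than in NOMO-1, the 2 arrays of high median signal. These gaps rest on 1 array each and carry no test.

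Erythroid genes, such as TAL1 and KLF1, scored highest in SET2 (3.28), HEL (2.94) and OCI-M2 (2.88), and lowest in EOL-1 (-1.48). SET2, HEL and OCI-M2 with MOLM-16, F-36P and OCI-M1 lay at 2.04 or above and the next unit, GF-D8, at 0.809, a gap of 0.259 of the range. Megakaryocyte and platelet genes, with RAB27B and ITGA2B the most variable, were highest in HEL (2.56) and SET2 (1.6). Granule genes were highest in SHI-1 (2.64) and HL-60/PLB-985 (2.54) and lowest in HNT-34 (-3.07). Monocyte genes, led by S100A8 and S100A9, were highest in NOMO-1 (2.72), an array of high median signal, and lowest in OCI-M2 (-1.62). Stem and progenitor genes, with SPINK2 and KIT the most variable, were highest in GDM-1 (3.08) and lowest in ML-2 (-1.83), and both of these arrays had a high GAPDH ratio.

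**Figure D3:**
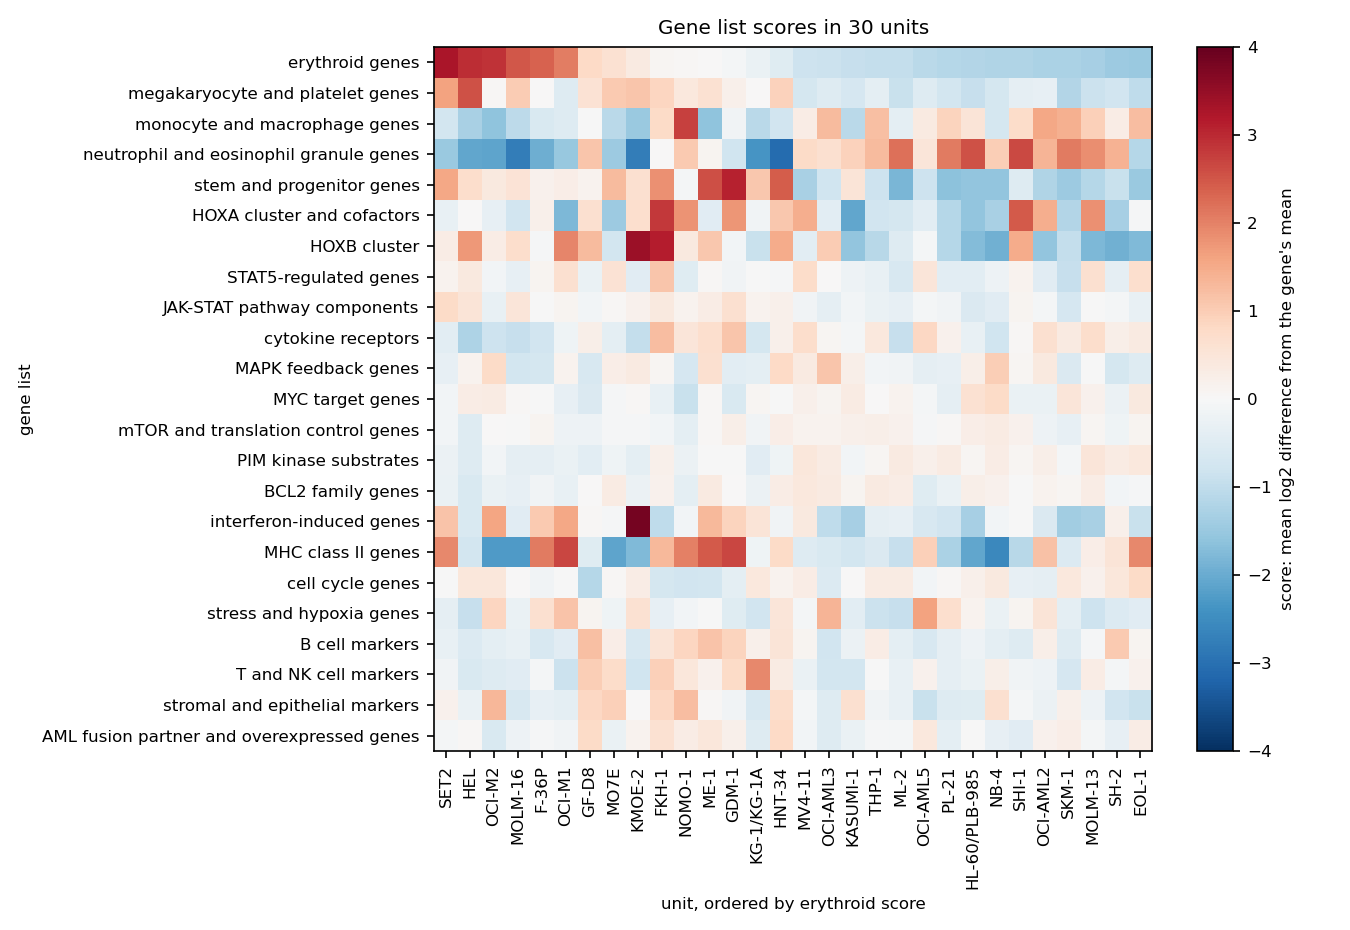
Score of each of 23 gene lists (y axis) in 30 units (x axis, ordered by erythroid score), as the mean log2 difference from each gene's mean over units, red above and blue below 0. The erythroid score runs from 3.28 in SET2 to -1.48 in EOL-1, and the interferon score is highest in KMOE-2 at 3.84.

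The lineage scores were related to each other over the 30 units. Erythroid scores rose with megakaryocyte scores (r = 0.709, rho = 0.813, permutation p = 7e-05, adjusted p = 0.000647) and fell with granule scores (r = -0.685, rho = -0.7, adjusted p = 0.000647) and monocyte scores (r = -0.554, rho = -0.608, adjusted p = 0.00622). Megakaryocyte scores rose with stem and progenitor scores (r = 0.704, rho = 0.844, adjusted p = 0.00037), and monocyte with granule scores (r = 0.634, rho = 0.646, adjusted p = 0.00132). Megakaryocyte scores fell with monocyte scores (r = -0.476, adjusted p = 0.0194) and granule scores (r = -0.653, adjusted p = 0.000802). Stem and progenitor scores fell with monocyte scores (r = -0.527, adjusted p = 0.0084) and granule scores (r = -0.64, adjusted p = 0.000802). Erythroid with stem and progenitor scores passed by rank alone (rho = 0.628, adjusted p = 0.00199; r = 0.383, adjusted p = 0.0628). Of all 37 relations in the family, 19 passed by Pearson, 18 by Spearman and 16 by both. Without the 2 farthest units, these 9 relations that passed by Pearson had r of the same sign. In the 23 units of low GAPDH ratio r was 0.686 to 0.738 for the relations that rose and -0.724 to -0.623 for those that fell. In the 8 arrays of high ratio the monocyte relations did not hold, since r was 0.155 with erythroid, 0.328 with megakaryocyte, 0.0537 with granule and 0.0266 with stem and progenitor scores (exact permutation p = 0.701, 0.45, 0.891 and 0.945). The other 5 had the same sign there, from r = -0.789 for stem with granule scores to 0.948 for erythroid with megakaryocyte scores. In the 24 units below the gap in erythroid scores, r of that score was 0.889 with megakaryocyte, -0.524 with granule and -0.395 with monocyte scores (permutation p = 1e-05, 0.00894 and 0.0562). In the 6 above it, r was 0.702, 0.075 and -0.469 (exact permutation p = 0.121, 0.876 and 0.338).

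STAT5-regulated genes, taken as a list, were higher in lines with more PIM1. CISH, a feedback inhibitor of cytokine signalling, had a slope of 0.34 ± 0.063 log2 units per log2 unit of PIM1 over the 30 units (adjusted p = 0.0593). SOCS1 had one of 0.45 ± 0.097, SOCS2 of 0.49 ± 0.13 and ID1 of 0.51 ± 0.14 (adjusted p = 0.195, 0.34 and 0.397). Adjusted over the list alone, 6 of the 15 STAT5-regulated genes rose and 0 fell, with p = 0.000115 for CISH, 0.000421 for SOCS1, 0.00348 for SOCS2 and 0.00436 for ID1; adjusted over all genes, 0 passed. The list rose by camera (11 of 15 slopes positive, adjusted p = 2.04e-05), with adjusted p = 0.000732 with an estimated correlation.

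Granule genes went the other way. They fell with PIM1 (14 of 15 slopes negative, camera adjusted p = 4.1e-09), with adjusted p = 0.043 with an estimated correlation. MPO had a slope of -1.06 ± 0.27, CEBPE, a transcription factor of granulocytes, of -0.45 ± 0.13, CTSG (cathepsin G) of -0.69 ± 0.22 and AZU1 (azurocidin) of -0.77 ± 0.28. Adjusted over the list alone 8 fell, and over all genes 0 passed.

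The erythroid list also rose with PIM1 (17 of 17 positive, camera adjusted p = 2.15e-10; adjusted p = 0.19 with an estimated correlation), with slopes of 0.60 ± 0.22 for TAL1 and 0.51 ± 0.20 for HBD (delta globin). So did the megakaryocyte list (15 of 18 positive, adjusted p = 4.86e-05; adjusted p = 0.242 with an estimated correlation), where TUBB1 had a slope of 0.30 ± 0.12. The stem and progenitor list rose (15 of 18 positive, adjusted p = 7.38e-05; adjusted p = 0.242 with an estimated correlation), with 0.56 ± 0.18 for MECOM. The MHC class II list rose (10 of 11 positive, adjusted p = 3.89e-05; adjusted p = 0.242 with an estimated correlation), with 0.58 ± 0.24 for HLA-DRA. In these 4 lists 0 genes passed by limma, adjusted over the list alone or over all genes. Over all genes 1101 had an unadjusted p under 0.05. Of 100 orders of the PIM1 values, the real one included, 32 gave at least as many lists as the 6 that passed camera, and 1 gave as many as the 2 with an estimated correlation.

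Over all 15454 genes, 1 rose with PIM1 and 0 fell. It was APOL4, of the apolipoprotein L family, with a slope of 0.61 ± 0.083 (adjusted p = 0.000313), highest in FKH-1 at 9.65 and lowest in SKM-1 at 4.41. APOL4 lost its call among lines in RPMI 1640 without cytokine (adjusted p = 0.192). The count was 2 without EOL-1, MOLM-13, ME-1 or HEL and 3 without MOLM-16, GF-D8 or OCI-M2, with APOL4 among the genes each time.

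The other 17 lists did not pass with PIM1. Adjusted p was 0.0577 for T and NK cell markers, 0.0716 for MAPK feedback, 0.0782 for MYC targets, 0.138 for HOXB and 0.166 for JAK-STAT components. It was 0.421 each for the monocyte, HOXA, mTOR and interferon lists, 0.469 for PIM substrates, 0.51 for cytokine receptors and for AML fusion partner genes, and 0.661 for BCL2 family and stromal genes. B cell, stress and cell cycle lists had 0.851, 0.981 and 0.985. Adjusted over the list alone, 1 PIM substrate rose and 1 fell, and 1 stress gene fell, while over all genes 0 did.

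The genes that rose with PIM2 included several of erythroid cells. Over the 30 units 112 genes rose and 117 fell with PIM2 (limma, 15454 genes, 229 in all), and 2998 had an unadjusted p under 0.05. Among the genes that rose most were HBZ (zeta globin), with a slope of 1.93 ± 0.41, KLF1, an erythroid transcription factor gene, with 1.91 ± 0.43, CA1 (carbonic anhydrase 1) with 1.91 ± 0.42 and HBBP1, a pseudogene of the beta globin cluster, with 2.18 ± 0.50. The others were BEX4, MYL4, HEPH, NMU, DNAJC6 and AKR1C2, with slopes from 1.80 to 2.08. Of the 17 erythroid genes, 17 had positive slopes, 5 rose over all genes and 14 rose adjusted over the list alone. The list rose by camera (adjusted p = 2.34e-13), a call lost at adjusted p = 0.1 with an estimated correlation and kept with fry (adjusted p = 0.00612).

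The genes that fell with PIM2 included MPO and CSF3R. MPO had the steepest slope, -2.55 ± 0.67 (adjusted p = 0.0482), and PARVG, a parvin gene of leukocytes, the smallest p of those named (slope -1.80 ± 0.32, adjusted p = 0.0115). RASSF4, SLC2A5 (a fructose transporter gene), PRAM1, TIMP2, IMPA2, NOG, EVI2A and MDFIC had slopes from -2.01 to -1.75. In the granule list 12 of 15 slopes were negative and 2 genes fell over all genes, MPO and CSF3R (-1.35 ± 0.32), and 8 fell adjusted over the list alone. The list fell by camera (adjusted p = 0.00132), with adjusted p = 0.576 with an estimated correlation and 0.0462 with fry.

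A few genes of cytokine signalling passed with PIM2, while the JAK-STAT component list (camera adjusted p = 0.344) and the cytokine receptor list (0.233) did not. JAK2, the kinase of erythropoietin and thrombopoietin receptors, rose with a slope of 1.10 ± 0.22 (adjusted p = 0.0176), the survival gene BCL2L1 with 0.68 ± 0.18 and ID1 with 1.37 ± 0.34, while the repressor gene BCL6 fell with -1.03 ± 0.27. The STAT5-regulated list rose (12 of 15 positive, camera adjusted p = 0.0121), with adjusted p = 0.1 with an estimated correlation and 0.00612 with fry. In it 2 genes were higher and 1 lower, both over all genes and adjusted over the list alone. Adjusted over their lists alone, 2 JAK-STAT components rose and 1 fell, and 2 cytokine receptors rose and 4 fell, against 1 risen and 1 fallen over all genes.

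In addition, 5 more lists passed camera with PIM2, and none of these did so with an estimated correlation. The megakaryocyte list rose (16 of 18 positive, adjusted p = 0.0049; adjusted p = 0.626 with an estimated correlation), although FLI1 had a slope of -1.20 ± 0.37 and passed adjusted over the list alone. The monocyte list fell (16 of 20 negative, adjusted p = 0.0158; adjusted p = 0.626 with an estimated correlation), with S100A8 at -2.08 ± 0.67 but FCGR2A at 1.09 ± 0.31. The HOXB list (7 of 8 positive, adjusted p = 0.0049; adjusted p = 0.626 with an estimated correlation) and the interferon list (16 of 22 positive, adjusted p = 0.0195; adjusted p = 0.626 with an estimated correlation) rose. The cell cycle list rose (18 of 23 positive, adjusted p = 0.0158; adjusted p = 0.626 with an estimated correlation) with 1 gene passing over all genes, BUB1 (0.63 ± 0.15), but without the 8 arrays of high GAPDH ratio it was lower, with adjusted p = 0.933. Adjusted over the list alone, 1 megakaryocyte gene rose and 1 fell, 1 monocyte gene rose and 3 fell, 2 HOXB genes rose, and 1 interferon and 1 cell cycle gene rose. The other 15 lists had adjusted p from 0.147 to 0.993; of their genes not yet counted, 4 stem and progenitor genes rose and 1 fell, and 1 rose and 1 fell among both BCL2 family and AML fusion partner genes, adjusted over the list alone.

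The PIM2 count depends on single lines and on the scaling. Without OCI-M1, the line richest in PIM2, limma called 0 genes, while 2759 had an unadjusted p under 0.05 and the slopes of the 229 kept their sign and a median of 1.04 of their size (SE 0.164). It called 79 without OCI-M2, 81 without HEL, 82 without F-36P, 93 without SET2, 124 without PL-21 and 405 without KMOE-2. With quantile normalization the monocyte (adjusted p = 0.0985), HOXB (0.0985), interferon (0.0985), STAT5-regulated (0.0763) and cell cycle (0.0664) lists no longer passed. With median centring the megakaryocyte (0.24), HOXB (0.416), interferon (0.416) and STAT5-regulated (0.167) lists did not.

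Across units, PIM1 level went with the STAT5 score, and PIM2 level with the erythroid score. For PIM1 and the STAT5 score r was 0.685 and rho 0.65 (permutation p = 4e-05 and 0.00014, adjusted p = 0.000647 and 0.000863). It was 0.755 without MOLM-16 and KMOE-2, 0.682 in 23 units of low GAPDH ratio and 0.697 in the 8 arrays of high ratio (exact permutation p = 0.0316). For PIM2 and the erythroid score r was 0.621 and rho 0.47 (permutation p = 0.00031 and 0.00952, adjusted p = 0.00143 and 0.022), with 0.51 without OCI-M1 and HEL. This relation was 0.721 in the 23 units of low ratio and had the opposite sign, -0.771, in the 8 arrays of high ratio (exact permutation p = 0.0294). On the sides of the gap in erythroid scores r was -0.028 in the 24 units below (rho = 0.0278, permutation p = 0.897). It was -0.447 in the 6 above (exact permutation p = 0.381), so neither side alone showed the rise. A split on the score narrows its range, although in the same 24 units that score kept r = 0.889 with megakaryocyte scores (permutation p = 1e-05). PIM2 ran from 9.65 to 12.06 in the 6 and from 8.17 to 10.42 in the 24. The pooled r thus goes with mostly higher PIM2 in the 6, and a rise within either side was not seen. For PIM1 and the STAT5 score r was 0.749 in the 24 (adjusted p = 0.00037).

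**Figure D4:**
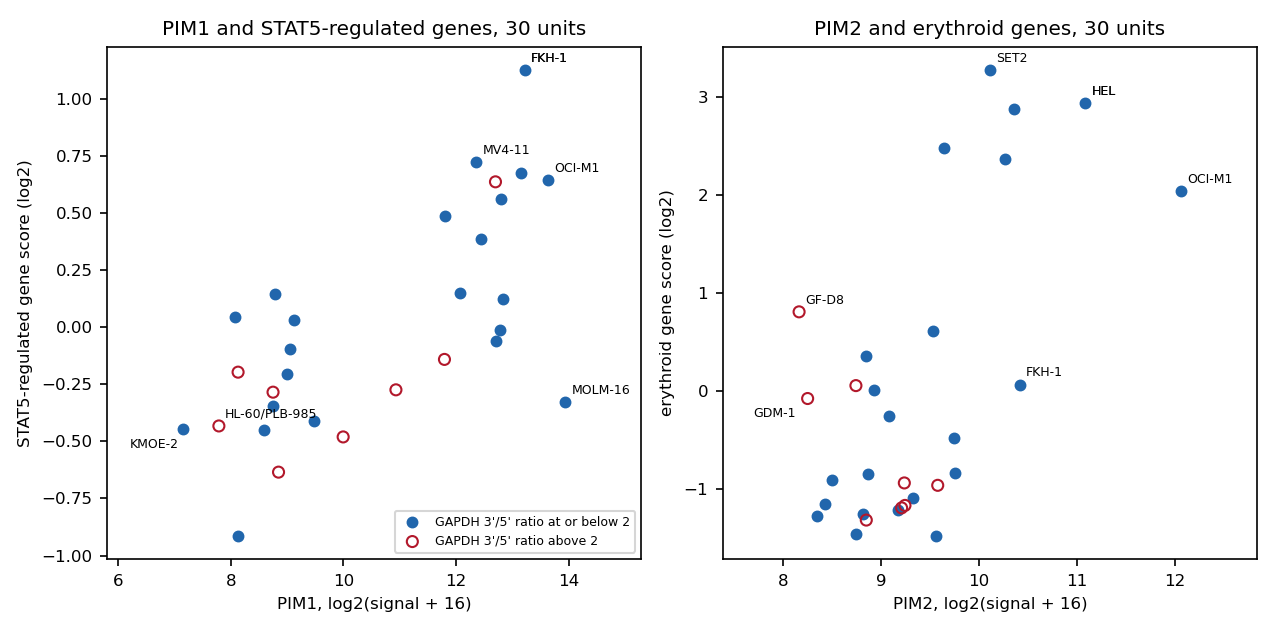
Left, STAT5-regulated gene score (log2) on the y axis against PIM1 level as log2(signal + 16); right, erythroid gene score against PIM2 level, 1 point per unit (30 units), with open circles for a GAPDH 3'/5' ratio above 2. The r is 0.685 on the left and 0.621 on the right, where the units rich in PIM2 include OCI-M1 and HEL.

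Other relations of the PIM genes passed with smaller r. PIM1 rose with PIM2 (r = 0.514, rho = 0.529, adjusted p = 0.0084), with r = 0.673 at low and -0.754 at high GAPDH ratio (exact permutation p = 0.0369). PIM1 fell with the granule score (r = -0.544, rho = -0.537, adjusted p = 0.0084) and rose with the erythroid score (r = 0.422, adjusted p = 0.0422; rho = 0.406, adjusted p = 0.0528). PIM2 rose with the STAT5 score (r = 0.557, rho = 0.574, adjusted p = 0.00493) and fell with the granule score (r = -0.494, rho = -0.499, adjusted p = 0.0123), which at high ratio had r = 0.766 (exact permutation p = 0.0214). PIM3 fell with PIM2 (r = -0.429, adjusted p = 0.0394; rho = -0.399, adjusted p = 0.0536) and rose with the granule score (r = 0.458, rho = 0.417, adjusted p = 0.0253). PIM3 with the erythroid score had r = -0.417 (adjusted p = 0.0431) and rho = -0.305 (adjusted p = 0.155), and with PIM1 r = -0.4 (adjusted p = 0.0532) and rho = -0.445 (adjusted p = 0.0308). In the 24 units below the erythroid gap, where that score's range is narrowed, r with it was 0.227 for PIM1 and 0.0187 for PIM3 (permutation p = 0.284 and 0.933), and of the relations in this paragraph only PIM2 with the STAT5 score passed there (r = 0.629, adjusted p = 0.00647). Without the 2 farthest units these relations had r of the same sign, with permutation p from 0.00021 to 0.0365. At low GAPDH ratio r was -0.559 for PIM1 and 0.644 for PIM2 with the granule and the STAT5 score in turn, 0.433 for PIM1 with the erythroid score, -0.547 for PIM2 with the granule score and -0.421 for PIM2 with PIM3. At high ratio these were -0.462, -0.293, 0.329, 0.766 and 0.214. For PIM3 with the granule score, the erythroid score and PIM1, r was 0.412, -0.466 and -0.35 at low and 0.136, 0.0568 and -0.607 at high ratio.

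Over the 30 units 43 genes rose and 45 fell with PIM3 (limma, 88 of 15454), and 2839 had an unadjusted p under 0.05. With median centring 45 rose and 1 fell. The genes that rose most were RPA4 (2.0 ± 0.39), a replication protein A subunit gene, and SLC75A1 (1.75 ± 0.27, adjusted p = 0.00378). ARRDC1, EME2, DGKZ (diacylglycerol kinase zeta), RIN1, ITGA5 (integrin alpha 5), RBP4, DAGLB and SLC12A9 had slopes from 1.22 to 1.48. AKR1C3, an aldo-keto reductase gene, fell most (-2.51 ± 0.61), followed by BLVRB (biliverdin reductase B, -2.27 ± 0.48). MCUB, LINC01806, CCNDBP1, NBDY, SH3BGR, ATPAF1, PLSCR1 and ZNF823 had slopes from -1.85 to -1.25. Of the 43 that rose 22 were highest, and of the 45 that fell 23 were lowest, in NOMO-1 or GF-D8, among them 8 and 4 of those named.

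The erythroid list fell with PIM3 (17 of 17 negative, camera adjusted p = 8.79e-06; adjusted p = 0.702 with an estimated correlation), with RHAG at -2.08 ± 0.62. The granule list rose (14 of 15 positive, adjusted p = 0.00199; adjusted p = 0.702 with an estimated correlation), with CEBPE at 1.84 ± 0.47 and MPO at 3.18 ± 1.08. The interferon list fell (18 of 22 negative, adjusted p = 0.0286; adjusted p = 0.725 with an estimated correlation), although MX2 had a slope of 1.29 ± 0.47. Of 100 orders of the PIM3 values, the real one included, 73 gave at least 3 lists. The granule list did not pass with median centring (adjusted p = 0.1), nor the interferon list with quantile normalization (0.082). With the log2 GAPDH ratio, r was 0.396 for the granule score (rho = 0.401, adjusted p = 0.595 over 23 lists) and -0.218 for the erythroid score (rho = -0.091, adjusted p = 0.595). Adjusted over the list alone, 1 erythroid gene fell, 2 granule genes rose and 0 interferon genes passed, and over all genes 0 of these lists' genes did. Among the other 20 lists, with adjusted p from 0.0839 to 0.903, 3 JAK-STAT components rose and 4 fell, 3 MYC targets rose and 1 mTOR gene rose, adjusted over the list alone.

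PIM3 moved with the GAPDH ratio, and without the 8 arrays of high ratio limma called 0 genes. The slopes of the 88 genes then kept a median of 0.644 of their size (SE 0.146). With the log2 GAPDH ratio as a covariate they kept 0.638 (SE 0.1). Leaving out 1 unit gave 3 genes without NB-4, 5 without GF-D8, 8 without HL-60/PLB-985 or OCI-M1, 11 without ML-2, 13 without HEL, 15 without SET2, 23 without OCI-M2, 24 without GDM-1, 32 without MOLM-16 or SH-2, 33 without THP-1 and 34 without F-36P, but 145 without ME-1, 154 without MO7E, 267 without OCI-AML5, 269 without KG-1/KG-1A and 403 without NOMO-1.

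PIM2 and PIM3 slopes were opposed. They shared 11 called genes, each with opposite signs. The levels of PIM2 and PIM3 themselves had r = -0.429, so this overlap is not independent of that relation and carries no test. Across 15453 genes the slopes had r = -0.815 for PIM2 with PIM3, 0.712 for PIM1 with PIM2 and -0.664 for PIM1 with PIM3, though genes are not independent replicates.

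The stress and hypoxia list was higher in the 4 cytokine lines than in 23 units (15 of 16 genes higher, camera adjusted p = 9.73e-07), with adjusted p = 0.0223 with an estimated correlation. Of 100 splits of the units, the real one included, 7 gave at least this 1 list with an estimated correlation, and 67 gave at least the 3 lists that passed without it. The hypoxia-induced genes ANKRD37 (log2 difference 1.67 ± 0.62), NDRG1 (2.24 ± 0.91), BNIP3 (2.47 ± 1.05) and ADM (2.60 ± 1.11) led it, with adjusted p = 0.864 each and 0.0914 adjusted over the list alone. The score was highest of the 30 units in OCI-AML5 (1.61) and OCI-AML3 (1.36). The other cytokine lines, F-36P (0.643) and OCI-AML2 (0.528), lay below OCI-M1 (1.13), OCI-M2 (0.864) and PL-21 (0.659). No cytokine was named for OCI-M1, OCI-M2 and PL-21, so the score did not separate the groups.

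The monocyte list rose too (16 of 20 higher, adjusted p = 0.00706; adjusted p = 0.82 with an estimated correlation), with KLF4 at 2.48 ± 0.90, FCGR2A at 2.19 ± 0.88, CD14 at 1.32 ± 0.67 and IRF8 at 2.31 ± 1.24. The cell cycle list fell (19 of 23 lower, adjusted p = 0.0131; adjusted p = 0.82 with an estimated correlation), with MCM2 at -0.58 ± 0.26 and CCNE2 at -0.96 ± 0.48. For single genes limma called 0 of 15455 (878 had an unadjusted p under 0.05, smallest adjusted p = 0.705), and 0 adjusted over any list alone. The other 20 lists had adjusted p from 0.126 to 0.886. Without OCI-AML2 only the stress and hypoxia list passed (monocyte adjusted p = 0.134, cell cycle 0.0974), without OCI-AML3 the cell cycle list did not (0.287), and with median centring it did not either (0.0792). Without F-36P 6 lists passed, and without OCI-AML5 1 gene did, HSD11B1-AS1, named after its value was seen. Cytokine, line and, for the 3 OCI-AML lines, alpha-MEM cannot be separated.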

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

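The limit of 2 on the GAPDH ratio was chosen after seeing the data, as were the tests that leave out arrays and set PIM3 slopes against each other here; the test on HL-60 and PLB-985 and the reordering test were fixed before their results were seen.

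Among the 4 lines grown with a cytokine, 1 line stood far from the other 3 in 2 of the 26 groups of values tested, and chance does this in about 1 in 20 groups. F-36P had an erythroid score of 2.37, with the next of the 4 at -0.846, a gap of 0.887 of the whole range. OCI-AML2 had a B cell marker score of 0.246, with the next at -0.629, a gap of 0.861 of the range. Both gaps exceed Dixon's 95% critical value for 4 samples.

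Control probe sets outside the comparisons set other arrays apart. The cre spike, a labelled transcript added during hybridization, gave a signal 7.52 times the median of arrays on NOMO-1 and 14.8 times on GF-D8. The GAPDH 3'/5' ratio was above 2 on 8 arrays, with 6.66 for GDM-1, 7.08 for HL-60, 5.97 for ML-2, 2.61 for MOLM-13, 6.84 for NB-4, 2.42 for THP-1, 2.84 for NOMO-1 and 4.45 for GF-D8, against at most 1.24 on the other 24.

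RNA degradation may account for part of the 88 genes associated with PIM3. Against the arrays of NOMO-1 and GF-D8 as the whole source, slopes without them kept a median of 0.916 of their size (SE 0.126), although the count of called genes was then 31. The 88 genes were called on data that hold the units kept, so such a ratio is partly built in. In the units of low GAPDH ratio the slopes kept 0.644 (SE 0.146), which neither excludes degradation as the whole source by the bound set for it nor shows it; the count of 0 there goes with smaller slopes and fewer arrays. HL-60, with a ratio of 7.08 and PIM3 at 12.39, differed from its subline PLB-985 (0.933 and 11.66) in the direction of the slope for 88.6% of the 88 genes, against 39.8% to 60.2% for random sets. KG-1 against KG-1A, both of low ratio with PIM3 at 10.35 and 9.357, gave 60.2%, just above random sets (38.6% to 59.1%), so the larger share goes with the pair that differs in ratio, while other differences between HL-60 and PLB-985, and a biological source, stay open and untested.

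For the number of PIM3 genes, 1 of 100 orders of the PIM3 values, the real one, gave as many as 88, and the highest of the others gave 1. This is the smallest share that 100 orders can give, and it is not adjusted over the reordering tests given here. It argues against chance for this count without excluding it, and it holds for the main setting alone. Chance cannot be excluded for the 3 lists, since 73 of 100 orders gave at least as many, up to 10.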

How the results depend on the processing

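Settings without NOMO-1 and GF-D8, without the 8 arrays of high GAPDH ratio, with the log2 GAPDH ratio as a covariate, without 1 unit at a time, cytokine lists without 1 line, lists with median centring, and correlations in the 24 units below the gap in erythroid scores were chosen after seeing the data; the rest were planned. APOL4 with PIM1 (1 gene) stayed past the threshold in every setting except a filter on the mean level, which does not test it, and lines in RPMI 1640 without cytokine, where fewer lines were used, with 0 genes each. The PIM1 count was 2 with median centring, the mean of probe sets, 32 lines, normal scores, the first principal component, or without NOMO-1 and GF-D8 or the 8 arrays; 3 with quantile normalization, the most variable probe set or a pseudocount of 1; 5 without the 2 farthest units (APOL4, CISH, DOK3, ME1 and SOCS1, named after their values were seen); and 1 to 3 without 1 unit. The 229 PIM2 genes became 1736 with quantile normalization, 4094 with median centring, 134 with normal scores, 123 without the 8 arrays, 16 with the GAPDH covariate (slopes kept a median of 0.922 of their size, SE 0.108), and 0 with the first principal component, without the 2 farthest units or in RPMI 1640 lines; without 1 unit they ran from 0 to 405. Median centring moved the median slope of all genes on PIM2 from -0.036 to 0.148 and on PIM3 from 0.0464 to 0.144, so most of the 4094 (86.3%) rose, against 48.9% of the 229. The 88 PIM3 genes became 1060 with quantile normalization, 541 with 32 lines, 257 with normal scores, 241 with the most variable probe set, 199 with the mean filter, 46 with median centring (45 higher, 1 lower), 32 with the mean of probe sets, 31 without NOMO-1 and GF-D8, 22 with no filter and 19 without a trend. PIM3 had 0 genes with the first principal component, with the GAPDH covariate, without the 8 arrays or in RPMI 1640 lines, and 3 to 403 without 1 unit. The 0 cytokine genes became 1 with the most variable probe set (GPNMB), 4 without the 8 arrays (COL8A2, FKBP5, PLEKHG4 and TAF15, named like GPNMB after their values were seen), and 0 to 1 without 1 line. Lists with PIM1 went from 6 to 2 with an estimated correlation and 2 with fry; with PIM2 from 8 to 0 and 3, 3 with quantile normalization and 5 with median centring (4 of the 8); with PIM3 from 3 to 0 and 0, 6 without NOMO-1 and GF-D8, 9 with the GAPDH covariate and 11 with median centring (2 of the 3); and with cytokine from 3 to 1 and 1, 5 with the GAPDH covariate, and 1 to 6 without 1 line. The STAT5-regulated list with PIM1 and the stress and hypoxia list with cytokine passed in every setting in which lists were run, with adjusted p from 4.29e-05 to 0.00209 for STAT5 under other data settings. Median centring ended the calls of 4 PIM2 lists, the granule list with PIM3 (adjusted p = 0.1) and the cell cycle list with cytokine (0.0792), and MYC targets (2.25e-07) and cell cycle genes (0.00436), the latter lower as deposited (0.0839), were then higher with PIM3. None of the 20 list calls turned direction under quantile normalization or median centring. Reversed were the PIM2 slopes of PIAS1 (0.0432, most variable probe set), STAT3 (-0.14) and PTPN1 (-0.0344, both with the first principal component) and FLI1 (0.0615, RPMI 1640 lines), none past the threshold over all genes, and the cell cycle list with PIM2, lower with adjusted p = 0.933 without the 8 arrays. Of 19 correlations, 6 passed in RPMI 1640 lines and 9 in the 24 units (10 in all there), where fewer lines were used; in the 24, chosen by that score and so of narrowed range, those of the erythroid score with PIM2 (-0.028) and PIM3 (0.0187) were reversed, neither past the threshold. KG-1 with KG-1A moved from rank 8 to 4 over all probe sets, HL-60 with PLB-985 from 3 to 11 and, with quantile normalization, to 5. With no filter 4 of the 15 line-restricted genes were shared. Except where stated, the cause was not tested. Counts for single genes were 1910 on the same side, 57 newly past and 327 no longer past the threshold; for single lists 744, 36 and 47; for correlations 354, 8 and 43. Other probe sets of the PIM genes as covariates were not run, since each gene has 1 listed probe set. Between 16.1% and 24.7% of probe sets had signals below 16 on 30 arrays, so differences among low signals are limited by background.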

Other observations

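The tests of degradation on PIM2 and on the STAT5-regulated genes, the test in 24 units, and the values without single units were chosen after the result was seen; the tests with the erythroid score as a covariate and the reordering tests were fixed before their results were seen.

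Interferon-induced genes marked 1 line. KMOE-2 had a score of 3.84 over 22 genes, with OCI-M2 next at 1.59 and SKM-1 lowest at -1.38. IFI27 was highest in KMOE-2 (13.09) with SET2 next (12.82), and XAF1 in NOMO-1 (13.55). KMOE-2 also had the highest HOXB score, 3.41, with FKH-1 at 3.15, and the homeobox genes HOXB2 and HOXB3 reached 12.49 in ME-1 and 12.67 in KMOE-2. The 3 tested genes of the HOXA list scored highest in FKH-1 (2.82), and of these MEIS1 and PBX3 were highest in SHI-1, at 11.86 and 13.05.

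MHC class II scores ranged widely between lines, without separate clusters. GDM-1 (2.67), OCI-M1 (2.67) and ME-1 (2.45) scored highest and NB-4 lowest (-2.59), and HLA-DRA ran from 4.41 in KMOE-2 to 14.32 in EOL-1. T and NK cell markers were highest in KG-1/KG-1A (1.92), with CD3D at 13.31 there and 13.38 in FKH-1. FLT3, a receptor kinase gene, was highest in MOLM-13 (13.17) and MV4-11 (13.06). BNIP3, a mitophagy gene induced by hypoxia, was at 4.12 in SHI-1 against 13.89 in OCI-AML5, and EPCAM, an epithelial marker, reached 13.27 in OCI-M2. These values rest on 1 array per line, or on 2 for KG-1/KG-1A, and carry no test.

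The erythroid character of some lines may account for part of the PIM2 genes. Against degradation as the whole source, slopes kept a median of 0.981 of their size (SE 0.0925) in units of low GAPDH ratio. Against NOMO-1 and GF-D8 they kept 0.988 (SE 0.0976) without them. The genes were called on data that hold the units kept, OCI-M1 and HEL among them. Ratios near 1 are thus partly built in and argue only weakly. HL-60, with PIM2 at 9.726 against 8.767 in PLB-985, differed from it in the direction of the slope for only 38.4% of the 229 genes (random sets 43.7% to 56.3%), so these genes went against PIM2 in that pair and a part played by degradation stays open. With the erythroid score as a covariate, the 224 called genes outside the erythroid list kept 0.61 of their slope (SE 0.166) and 0 genes were called. In the 24 units below the gap in erythroid scores they kept 0.458 (SE 0.16), again with 0 called. That split leaves out OCI-M1 and HEL, the units richest in PIM2, so smaller slopes and fewer calls can follow from the selection itself. Erythroid character as the whole source and a further link to PIM2 thus cannot be told apart.

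STAT5 activity is a candidate explanation for PIM1 and the STAT5-regulated genes going together, since PIM1 is itself a known STAT5 target. Degradation is argued against by r = 0.682 in units of low GAPDH ratio (permutation p = 0.00048). Erythroid character is argued against by a partial r of 0.686 given the erythroid score (permutation p = 2e-05). STAT5 activity itself was not measured, the relation was found and tested on the same lines, and a shared regulator other than STAT5 stays open.

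For PIM1, 3 of 100 orders, the real one included, gave as many as 1 gene, the highest other 1. This share is not adjusted over the reordering tests given here, so it argues against chance only weakly. Of 100 orders of the PIM2 values, 3 gave at least the real 229 genes, the real one included, a share that is not adjusted either. The highest other gave 3867, so chance is not excluded for this count. That number points to a structure of the lines whose source was not tested. Without OCI-M1 the count was 0, though the slopes kept 1.04 of their size (SE 0.164). For the 8 PIM2 lists 4 of 100 orders gave as many, the highest other 9. Chance cannot be excluded for the number of PIM1 lists, where 32 orders gave at least 6 and the highest other 11; random orders passed a median of 4 lists at the preset correlation. With an estimated correlation, 1 of 100 orders, the real one, gave as many as 2 PIM1 lists, and the highest other gave 1. For cytokine, 100 of 100 splits gave at least the real 0 genes, as any split must, so this count tests nothing; the highest other gave 1998, which points to a structure of the lines whose source was not tested. Chance cannot be excluded for the 3 lists, since 67 splits gave at least as many (highest other 11). With an estimated correlation 7 splits gave as many lists as the real 1, with 1 also the highest of the others, so chance cannot be excluded for the number of cytokine lists.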
